A study of Rattus norvegicus with 24 samples.

How the data were processed

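Messenger RNA was measured in 3 tissues of male Wistar rats, an outbred laboratory strain: brown adipose tissue from between the shoulder blades (BAT), the heat-producing fat; white adipose tissue from around the kidney (WAT), a storage fat; and liver. Per the labels, the rats were 7 weeks old at the start and had access to food only from hour 10 to hour 16 of each day for 7 days. On day 8, 4 rats were fed again and 4 were not, so that the fasted rats had been without food for 24 h when the tissues were taken at hour 16. The labels number the fed animals 1, 2, 4 and 5 and the fasted animals 6, 8, 9 and 10, and each number has 1 array per tissue, which gives 24 arrays in 6 groups of 4. Equal numbers are taken to mark the same animal in the 3 tissues, which the labels do not say in words. Each array therefore stands for a separate animal within its group.

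Per the labels' protocols, labelled cRNA was made from 2 µg of total RNA. The deposited values are probe set intensities on a linear scale, 1 per probe set of an Affymetrix rat expression array, made by the authors with the MAS5 algorithm per the file headers; the MAS5 version is not given in the sources used here. No deposited value was 0 or negative. The deposited intensities had not been brought to a common level: the 2% trimmed mean of the 24 arrays ran from 93.4 to 206. Everything from here on was computed from these intensities. Each array was scaled to a common 2% trimmed mean of 129, and log2(signal + 1.9) was taken, where the pseudocount of 1.9 is the 10th percentile of all signals. Changes are given on this scale, which understates those of dim genes. The 57 control probe sets of the 31099 were left out, which left 31042. Of these, 20826 carried 1 gene symbol in the platform annotation, 436 carried several and 9780 were unnamed here. Symbols were updated through gene identifiers (20758 probe sets) or accessions (2), and 66 kept the symbol of the annotation. Of the 14217 named genes, 4525 had several probe sets; each gene is represented by its probe set with the highest mean log2 signal. Genes were tested where their mean log2 signal lay above the 40th percentile of all probe sets on the arrays of the fit. Genome coordinates were not used here.

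Fed and fasted arrays were compared within each tissue with limma 3.58.1 in R 4.3.3 (linear models with moderated variances and a mean-variance trend, two-sided, Benjamini-Hochberg adjustment over all genes tested). A gene is called where its adjusted p is under 0.05; "rose" and "fell" are used of such genes alone. Differences of the fasting effect between tissues were tested as interaction terms over all 24 arrays with 6 group means, and fed BAT was compared with fed WAT over their 8 arrays. Lists of pathway genes (29) and of markers of other cell types (10) were tested with camera in limma at a preset inter-gene correlation of 0.01, where a tissue kept at least 5 members; these were 34 lists per tissue and 102 tests, adjusted together. Beside each list stands the adjusted p with a correlation estimated per list, and the number of members called when p is adjusted over the list alone. None of the 40 list calls held with the estimated correlation. With fry, another list test of limma, 37 of the 40 held and 3 ended. It asks if the genes of a list changed, while camera asks if they changed more than other genes. The tests, samples, lists and rules for naming genes were fixed before the data were examined. The rule takes, per tissue, the 8 largest rises and the 8 largest falls among called genes whose fed and fasted arrays do not overlap; 12 genes fixed by name, of which 9 are reported here; and up to 4 members of each list described, in order of their p. For each difference between tissues it takes the 6 largest differences each way. Other genes are said to be chosen after their values were seen.

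Error is given as the SD of 4 arrays for signals and as the standard error of the fit for log2 changes. Arrays have no read depth, and the number of arrays limits the precision. The fits were tested on simulated data with the real genes' means and spreads: of genes given a log2 change of 1, 75% were recovered in BAT (10328 genes), 58.5% in WAT (10264 genes) and 67.2% in liver (10239 genes). For a log2 change of 0.5 these shares were 25.8%, 14.9% and 4.5%, for a change of 2 they were 96.9%, 98.3% and 90.3%, and false calls made up 4.9%, 4.4% and 4.5% of the calls. The simulated noise was independent between probe sets, without shared variation such as muscle content or scan day. Far fewer genes were changed than were called on the real arrays. These shares therefore need not hold for the real data. Pearson's r between replicate arrays, across probe sets, ran from 0.924 to 0.96.

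The experiment files give 2 batches. BAT and liver were scanned on 2 days that each held 2 fed and 2 fasted arrays; WAT was scanned on the same kind of 2 days (2 fed and 1 fasted array, then 2 fed and 2 fasted) with fasted animal 9 alone on a further day. Fed arrays were washed in fluidics modules 1 and 2 and fasted arrays in modules 3 and 4, except for the WAT array of fasted animal 9, in module 1. Scan day was fitted as a block and module as a random block. The numbers were taken to pair the arrays across tissues. Of 24 pairs of arrays with the same number, 20 deviated from their group means most like their own number. Their correlations ran from 0.01 to 0.19 (median 0.09, 10 above 0.1). Except for WAT of fasted animal 9, arrays of equal number shared the module and the order of the scan day in the 3 tissues. Shared processing could give this pattern too, so it does not show that equal numbers mark 1 animal. The animal was fitted as a block in the comparisons between tissues as an alternative. Other alternatives were other scalings, pseudocounts, filters and probe set summaries, a fit without the variance trend, all arrays in one model, other list tests (fry, from limma) and leaving out each animal in turn. A covariate for skeletal muscle or lymphocyte markers, leaving out genes that followed the muscle markers, leaving out the WAT arrays of animals 8 and 10, and each scan day alone were added after seeing the data. Figures were drawn with matplotlib 3.10.9, and tables were prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.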

Results

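The effect of a 24 h fast on mRNA was measured in BAT, WAT and liver of rats, with 4 fed and 4 fasted arrays per tissue. The labels give the same 8 animal numbers in each tissue, and equal numbers are taken to mark the same animal. Signals are scaled MAS5 intensities given as mean ± SD of n = 4 arrays. Log2 changes are fasted minus fed, ± SE. The 2% trimmed means of the arrays ran from 93.4 to 206 before scaling. Genes known as tissue markers had these levels in the fed groups. Ucp1, the uncoupling protein of brown fat mitochondria, had a signal of 11500 ± 1310 in fed BAT, 11.5 ± 9.9 in WAT and 3.68 ± 2.58 in liver. Adipoq, which encodes the fat hormone adiponectin, was at 4930 ± 384 in BAT, 6190 ± 814 in WAT and 5.3 ± 4.51 in liver. Apoa1, a lipoprotein gene of the liver, was at 6460 ± 690 in liver, 13.2 ± 10.1 in BAT and 5.16 ± 4.26 in WAT. Alb, the serum albumin gene of the liver, was at 11400 ± 1530 in liver, 2460 ± 370 in BAT and 1920 ± 494 in WAT.

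In BAT, 15 of 18 cholesterol, 11 of 18 fatty acid and 6 of 10 triglyceride synthesis genes fell with fasting, and 9 of 15 insulin signalling and FoxO target genes, 9 of 18 autophagy and ubiquitin ligase genes and 7 of 12 glucocorticoid response genes rose. The calls of these lists did not hold with an estimated correlation (adjusted p from 0.105 to 0.216). Pnpla3, a lipid droplet acyltransferase and lipase, changed by -3.81 ± 0.18, from 2340 ± 300 to 168 ± 41.7 (adjusted p = 2.15e-06). Klf15, a transcription factor of amino acid and glucose metabolism, rose by 3.43 ± 0.31, from 88.9 ± 45.7 to 886 ± 90.9 (adjusted p = 4.91e-05). The 8 largest rises by the naming rule, from 6.11 to 6.56, were of genes known from striated muscle. Ucp1 was at 11500 ± 1310 in fed and 10700 ± 398 in fasted BAT (-0.09 ± 0.08, adjusted p = 0.451), signals at which saturation was not excluded.

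Of 18 cholesterol synthesis genes tested in BAT, 15 fell, 1 rose and 2 did not pass, with the same numbers when adjusted over the list alone. Nsdhl, a sterol dehydrogenase, changed by -1.73 ± 0.12, from 1290 ± 192 to 384 ± 34.4. Fdps, which makes farnesyl diphosphate, changed by -1.37 ± 0.11. The list's median change was -1.39 (adjusted p = 1.59e-09; adjusted p = 0.105 with an estimated correlation). Of 18 fatty acid synthesis genes, 11 fell, none rose and 7 did not pass, with 12 falls when adjusted over the list alone. The desaturase Scd2 changed by -2.08 ± 0.12, from 1170 ± 122 to 276 ± 38.4. The elongase Elovl6 changed by -1.88 ± 0.09, from 5130 ± 319 to 1400 ± 108. The median of this list was -0.57 (adjusted p = 1.56e-08; adjusted p = 0.105 with an estimated correlation). Fasn, the fatty acid synthase, was at 10500 ± 952 in fed and 9730 ± 389 in fasted BAT (-0.1 ± 0.08, adjusted p = 0.365), where saturation was likewise not excluded. Srebf1, a transcription factor of lipid synthesis, was at 1920 ± 244 and 1760 ± 47.3 (-0.11 ± 0.1, adjusted p = 0.452). In triglyceride synthesis 6 of 10 genes fell and none rose by either adjustment (median -0.42, adjusted p = 0.00155; adjusted p = 0.216 with an estimated correlation). Gpam, a mitochondrial glycerol phosphate acyltransferase, changed by -2.72 ± 0.48, and Agpat2, another acyltransferase of this pathway, by -0.93 ± 0.07. Of 8 pentose phosphate and NADPH genes 4 fell and none rose, with 5 falls when adjusted over the list alone. Their median was -0.39 (adjusted p = 0.0023; adjusted p = 0.105 with an estimated correlation). Pgd, an NADPH-forming enzyme, changed by -1.02 ± 0.1, from 4800 ± 296 to 2380 ± 329.

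Among the 15 insulin signalling and FoxO target genes in BAT 9 rose and none fell, with 10 rises when adjusted over the list alone. Their median was 0.78 (adjusted p = 3.61e-05; adjusted p = 0.105 with an estimated correlation). Besides Klf15, Irs2, an insulin receptor substrate, rose by 2.66 ± 0.24, from 46.5 ± 12.5 to 309 ± 110. Among 18 autophagy and ubiquitin ligase genes 9 rose and none fell, or 9 and 1 when adjusted over the list alone. The median was 0.44 (adjusted p = 0.000949; adjusted p = 0.105 with an estimated correlation). Bnip3, a mitophagy receptor, rose by 1.21 ± 0.13, from 1500 ± 246 to 3470 ± 458. Trim63, a ubiquitin ligase of muscle, rose by 4.88 ± 0.72, from 9.57 ± 14.2 to 208 ± 99.4. Of 12 glucocorticoid response genes 7 rose and 1 fell by either adjustment (median 1.11, adjusted p = 0.000744; adjusted p = 0.216 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 2.46 ± 0.15, from 116 ± 20.7 to 640 ± 74.6. On the same arrays the mean log2 level of skeletal muscle markers was 7.22 ± 3.05 in fed and 12.04 ± 0.2 in fasted BAT.

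Of 17 circadian clock genes in BAT 8 rose and 3 fell by either adjustment (median 0.46, adjusted p = 0.0497; adjusted p = 0.216 with an estimated correlation). The list's call also ended under 10 other settings, with adjusted p from 0.0538 (quantile normalization) to 0.117 (mean of probe sets), among them scan day as a block (0.069) and the fits without fed animal 4 (0.0582), fed animal 5 (0.0563) or fasted animal 9 (0.0894). The clock repressors Per1, Per2 and Per3 rose by 1.81 ± 0.29, 1.29 ± 0.17 and 2.08 ± 0.3. Among 15 genes of thermogenesis and brown adipocyte identity 5 fell and none rose, with 6 falls when adjusted over the list alone. The median was -0.23 (adjusted p = 0.0188; adjusted p = 0.284 with an estimated correlation), and the call also ended under 6 other settings, with adjusted p from 0.0503 (quantile normalization) to 0.2 (muscle marker level as a covariate). Prdm16, a regulator of brown fat identity, changed by -1.91 ± 0.24, from 114 ± 23.1 to 29.6 ± 9.33. Dio2, which activates thyroid hormone, changed by -2.58 ± 0.66, from 119 ± 23.9 to 30.9 ± 38.1. Of 17 glycolysis and glucose uptake genes 3 rose and 6 fell, or 4 and 7 when adjusted over the list alone, and the list was not called (adjusted p = 0.259). Pfkfb3, which sets the level of a glycolytic activator, rose by 2.35 ± 0.13, and the insulin-regulated glucose carrier Slc2a4 fell by 0.56 ± 0.08. Of 10 xenobiotic metabolism genes 3 rose and none fell by either adjustment (median 0.21, adjusted p = 0.0394; adjusted p = 0.368 with an estimated correlation). That call also ended under 6 other settings, with adjusted p from 0.0527, without fed animal 1, to 0.314, without a filter, and at 0.0716 without fasted animal 6. The median of these genes was 0.07 with the muscle marker level as a covariate (adjusted p = 0.0957) and 0.08 on the first scan day alone (adjusted p = 0.211). Among these genes Cyp2e1, an acetone- and ethanol-oxidising cytochrome, rose by 4.31 ± 0.26, from 60.3 ± 19.2 to 1220 ± 309. The muscle marker level, 7.22 ± 3.05 in fed and 12.04 ± 0.2 in fasted BAT, moved with these lists as well.

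Genes of contracting muscle were high on the 4 fasted BAT arrays and on the array of fed animal 5. Of 14 skeletal muscle markers 13 rose by either adjustment (median 5.59, adjusted p = 1.59e-05; adjusted p = 0.438 with an estimated correlation). Ckm, the muscle creatine kinase, was at 1770 ± 3420 in fed and 8640 ± 849 in fasted BAT (6.56 ± 1.78, adjusted p = 0.0207; adjusted p = 0.0578 without fed animal 4). Mb, which encodes myoglobin, rose from 277 ± 186 to 1260 ± 343 (2.34 ± 0.36, adjusted p = 0.00114). The mean log2 level of the markers was 7.12, 5.68, 4.57 and 11.52 in fed animals 1, 2, 4 and 5. Of 13 macrophage markers 6 rose and none fell by either adjustment (median 0.45, adjusted p = 0.0164; adjusted p = 0.51 with an estimated correlation). This call ended on the first scan day alone (adjusted p = 0.136) and with the muscle covariate (adjusted p = 0.107). Cd68, a lysosomal protein gene of macrophages, rose from 152 ± 26.2 to 288 ± 15.2 (0.93 ± 0.14).

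**Figure D1:**
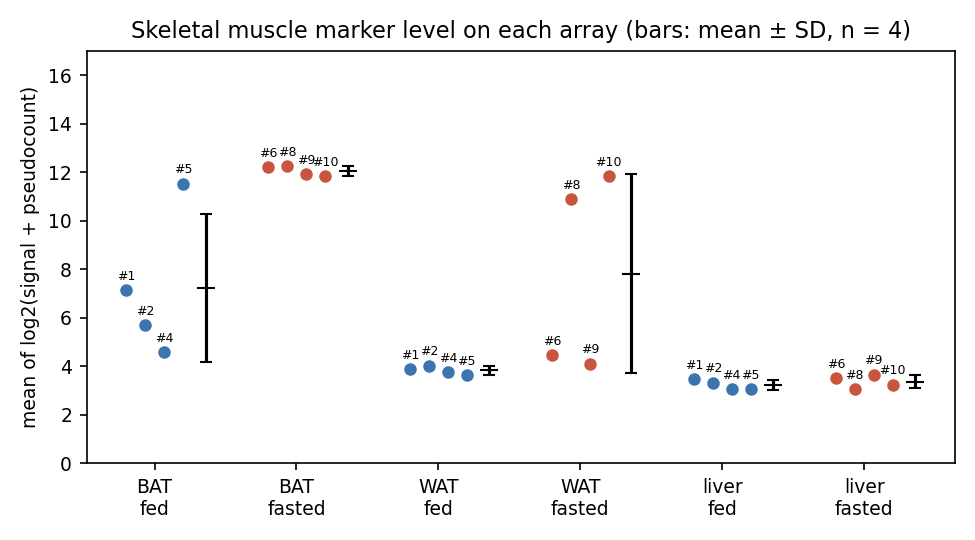
Mean log2(signal + pseudocount) of the 14 fixed skeletal muscle markers on each array, by group, with the animal number at each point and bars for the mean ± SD of n = 4 arrays. The fasted BAT arrays lie between 11.83 and 12.23, fed BAT runs from 4.57 to 11.52, and the WAT arrays of fasted animals 8 and 10 lie at 10.87 and 11.83, while the other WAT arrays and the liver arrays lie at or under 4.46.

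Of 10341 genes tested in BAT 2780 were called, 1424 higher and 1356 lower, and 489 and 281 of these changed at least 2-fold. Fed and fasted arrays did not overlap at 28.97% of genes, against 2.86% by chance. The actin 3'/5' log2 ratio, a sign of RNA quality, was 1.46 ± 0.47 in fed BAT, with 1.93 and 1.8 in animals 1 and 4, and 0.97 ± 0.09 in fasted BAT. That of Gapdh was 0.26 ± 0.02 and 0.3 ± 0.03. With scan day as a block 3506 genes were called, on the first scan day alone 1203 and on the second 1878. The 12 lists called became 13 with that block and 9 and 14 within the days. With the block the circadian clock was lost (adjusted p = 0.069). The tricarboxylic acid cycle (adjusted p = 0.0432) and the respiratory chain (adjusted p = 0.0497) were gained. With the muscle marker level as a covariate, chosen after seeing the data, 372 genes were called. Leaving out the genes that followed the muscle markers in WAT, also chosen after seeing the data, gave 2663 calls among 10123 genes, with 99.24% of the calls still tested kept. This run only drops genes, and the others keep their log2 changes. A high share kept follows from that and does not test the effect of muscle on them. The covariate fit kept the calls of Pnpla3, Klf15, Irs2, Scd2 and Fkbp5. It ended those of Ckm (-0.37), Mb (1.27), Trim63 (2.56), Dio2 (-2.17), Per1 (1.37), Per2 (1.14) and Mybpc1 (1.34), with estimates smaller in size than in the main fit. The calls of Gpam (-3.11, against -2.72) and Cpt1a (1.12, against 0.99) ended too, with estimates that were not smaller. Marker level and feeding had a correlation of 0.79 in BAT, which can widen the errors of this fit. Calls lost with the covariate, and the drop to 372, can therefore reflect lower precision as well as muscle. The calls of Mb (adjusted p = 0.0684) and Slc2a4 (adjusted p = 0.195) ended with all 24 arrays in one model and that of Per2 with the mean of probe sets (adjusted p = 0.183). On the first scan day alone those of Ckm (adjusted p = 0.277), Mb (adjusted p = 0.078), Mybpc1 (adjusted p = 0.179) and Dio2 (adjusted p = 0.183) ended.

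In WAT, 16 of 18 cholesterol, 11 of 18 fatty acid and 5 of 10 triglyceride synthesis genes, 7 of 17 glycolysis and glucose uptake genes and 6 of 14 tricarboxylic acid cycle genes fell with fasting. The calls of these lists did not hold with an estimated correlation (adjusted p from 0.105 to 0.506). Pdk4, the kinase that switches off pyruvate dehydrogenase, rose by 4.56 ± 0.21, from 78.1 ± 14.3 to 1920 ± 485 (adjusted p = 4.57e-06). Mvd, a decarboxylase of sterol synthesis, changed by -3.49 ± 0.22, from 191 ± 24.3 to 15.7 ± 4.93 (adjusted p = 2.1e-05). Ppp1r3b, which targets a phosphatase to glycogen, changed by -3.22 ± 0.13, from 857 ± 76.4 to 90.9 ± 13 (adjusted p = 2.12e-06). Lep, which encodes the satiety hormone leptin, was at 725 ± 435 in fed and 204 ± 98.9 in fasted WAT (-1.78 ± 0.44, adjusted p = 0.0217). The call of Lep ended under 4 settings, with adjusted p from 0.0601, without fasted animal 9, to 0.0708.

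Of 18 cholesterol synthesis genes in WAT 16 fell and none rose, with 17 falls when adjusted over the list alone. The median was -1.56 (adjusted p = 9.69e-15; adjusted p = 0.105 with an estimated correlation). Sqle, the squalene oxidase, changed by -2.73 ± 0.25, from 199 ± 53.7 to 28.6 ± 9.85, and Nsdhl by -2.27 ± 0.15. Of 18 fatty acid synthesis genes 11 fell and 1 rose by either adjustment (median -0.58, adjusted p = 4.18e-08; adjusted p = 0.216 with an estimated correlation). Mlxipl, which encodes the carbohydrate-responsive factor ChREBP, changed by -2.55 ± 0.17, from 847 ± 202 to 140 ± 12.6. Mid1ip1, an activator of acetyl-CoA carboxylase, changed by -2.31 ± 0.11. Fasn was at 7600 ± 1230 in fed and 6620 ± 827 in fasted WAT (-0.19 ± 0.13, adjusted p = 0.359), where saturation was not excluded either. Srebf1 was at 1480 ± 367 and 1140 ± 233 (-0.37 ± 0.2, adjusted p = 0.229; adjusted p = 0.0201 with scan day as a block). In triglyceride synthesis 5 of 10 genes fell and none rose, or 7 and 1 when adjusted over the list alone. The median was -0.63 (adjusted p = 0.000132; adjusted p = 0.317 with an estimated correlation), and Gpam changed by -2.49 ± 0.16. Of 8 pentose phosphate and NADPH genes 4 fell and 1 rose, or 6 and 1 when adjusted over the list alone. Their median was -0.46 (adjusted p = 0.00292; adjusted p = 0.408 with an estimated correlation).

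Among 17 glycolysis and glucose uptake genes in WAT 7 fell and 1 rose by either adjustment (median -0.34, adjusted p = 0.0199; adjusted p = 0.493 with an estimated correlation). This call also ended under 3 other settings, with adjusted p from 0.0529, without fasted animal 6, to 0.185, on the first scan day with its 1 fasted array. Slc2a4 changed by -1.53 ± 0.17, from 1980 ± 354 to 686 ± 142, and the hexokinase gene Hk2 by -1.88 ± 0.28. Pfkfb3 rose by 2.01 ± 0.21, from 529 ± 130 to 2120 ± 448. Of 9 glycogen metabolism genes 3 fell and none rose by either adjustment (median -0.18, adjusted p = 0.0394; adjusted p = 0.493 with an estimated correlation). The glycogen call also ended under 10 other settings. Apart from the first scan day with its 1 fasted array, adjusted p ran from 0.0535, without fed animal 4, to 0.102, without fasted animal 6. The list's median was -0.07 without fed animal 5 (adjusted p = 0.0573), -0.11 with quantile normalization and -0.29 with median centring. Of 14 tricarboxylic acid cycle genes 6 fell and none rose by either adjustment (median -0.27, adjusted p = 0.00298; adjusted p = 0.506 with an estimated correlation). Dlst, a subunit of the 2-oxoglutarate dehydrogenase complex, changed by -0.69 ± 0.13, from 903 ± 166 to 552 ± 18.7. Of 23 respiratory chain genes 4 fell and none rose by either adjustment (median -0.25, adjusted p = 0.000744; adjusted p = 0.572 with an estimated correlation; adjusted p = 0.12 with fry), with the cytochrome gene Cyc1 at -0.46 ± 0.11. Of 19 ribosome biogenesis genes 7 fell and 1 rose, or 8 and 1 when adjusted over the list alone. Their median was -0.31 (adjusted p = 0.00807; adjusted p = 0.469 with an estimated correlation), with the nucleolar protein gene Nop58 at -0.59 ± 0.1.

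Rises in WAT included 7 of 12 glucocorticoid response genes, with 1 fall, or 8 and 1 when adjusted over the list alone. The median was 0.93 (adjusted p = 0.00297; adjusted p = 0.216 with an estimated correlation). Fkbp5 rose by 1.51 ± 0.19, from 174 ± 44.5 to 494 ± 95.7, and Per1 by 1.46 ± 0.25. Of 16 autophagy genes 6 rose and none fell, or 6 and 1 when adjusted over the list alone. The median was 0.31 (adjusted p = 0.0196; adjusted p = 0.231 with an estimated correlation; adjusted p = 0.0626 without fed animal 1), and Bnip3 rose by 0.98 ± 0.11, from 2150 ± 244 to 4260 ± 428. With the muscle marker level as a covariate the list's median was 0.18 and its call ended (adjusted p = 0.0592), as it did on the first scan day with its 1 fasted array (adjusted p = 0.0651). The mean log2 level of skeletal muscle markers was 3.82 ± 0.17 in fed and 7.81 ± 4.1 in fasted WAT. The lipolysis and lipid droplet list was not called, with 3 rises and 1 fall among 15 genes, or 3 and 2 when adjusted over the list alone (adjusted p = 0.601). In it the beta-3 adrenergic receptor gene Adrb3 rose by 1.06 ± 0.19. G0s2, an inhibitor of the main triglyceride lipase, changed by -1.38 ± 0.18, from 4440 ± 933 to 1700 ± 353. Fgf21, a hormone gene, changed by -1.58 ± 0.25, from 55.8 ± 9.45 to 17.8 ± 5.97. Of 14 macrophage markers 4 rose and none fell, or 7 and none when adjusted over the list alone. Their median was 0.33 (adjusted p = 0.0102; adjusted p = 0.51 with an estimated correlation; adjusted p = 0.0625 without fasted animal 6). The list's call ended with fry as well (adjusted p = 0.0659). Cd163, a haemoglobin scavenger receptor of macrophages, rose by 1.19 ± 0.18.

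Skeletal muscle markers differed between the fasted WAT arrays. Their mean log2 level was 3.82 ± 0.17 in fed WAT, 4.46 and 4.1 in fasted animals 6 and 9, and 10.87 and 11.83 in fasted animals 8 and 10. Of 12 markers tested 1 rose by either adjustment (median 4.11, adjusted p = 0.00523; adjusted p = 0.572 with an estimated correlation). The list's median was 2.55 without fasted animal 8 (adjusted p = 0.0724) and 2.18 without fasted animal 10 (adjusted p = 0.18), which ended the call, as fry did (adjusted p = 0.163). Tnnc2, a fast muscle troponin gene, was at 6.19 ± 3.96 in fed and 2230 ± 2690 in fasted WAT (6.18 ± 1.49, adjusted p = 0.0188; adjusted p = 0.0503 without fasted animal 8). Ckm was at 2.11 ± 1.83 and 3100 ± 3810 (adjusted p = 0.0561; adjusted p = 0.0156 with scan day as a block).

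Of 10275 genes tested in WAT 1869 were called, 890 higher and 979 lower, and 220 and 228 of these changed at least 2-fold. Arrays did not overlap at 23.14% of genes, against 2.86% by chance. The share of calls that were higher was 47.62%, against 25.95% of 655 calls without scaling and 30.36% with median centring. These scalings moved the median change of all genes by -0.15 and -0.11, so changes in WAT are relative to the scaling. With scan day as a block 2098 genes were called, and 262 on the second scan day alone, with 2 fed and 2 fasted arrays. The first day held 2 fed arrays and 1 fasted array, that of animal 10, high in muscle markers; its fit gave 936 genes and 10 lists, takes the lone array to vary like the others and does not test replication. The 13 lists called became 12 with the block, without glycogen metabolism (adjusted p = 0.0672), and 17 on the second day. Without fed animal 5 1172 genes were called, and without fasted animals 8 and 10, left out for their muscle markers after seeing the data, 1044. On the second scan day alone the calls of Lep, Cpt1a, Hk2, Dlst, Cyc1, Nop58, Bnip3, Cd163, Fgf21 and Tnnc2 ended, with adjusted p from 0.0525 (Tnnc2) to 0.201 (Dlst). Without scaling those of Cpt1a (adjusted p = 0.0502) and Nop58 (adjusted p = 0.0848) ended.

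In liver, 11 of 13 genes of peroxisomal and omega oxidation, 12 of 19 of mitochondrial fatty acid oxidation and 6 of 13 of gluconeogenesis rose with fasting, and 14 of 18 fatty acid and 14 of 18 cholesterol synthesis genes fell. The calls of these lists did not hold with an estimated correlation (adjusted p from 0.0654 to 0.187). Igfbp1, a FoxO target that binds insulin-like growth factors, rose by 5.74 ± 0.41, from 85.2 ± 74 to 3870 ± 1150 (adjusted p = 6.66e-06). Cpt1a, which admits fatty acids to mitochondria, rose by 3.16 ± 0.22, from 613 ± 197 to 5370 ± 1090 (adjusted p = 4.86e-06). Fasn changed by -3.67 ± 0.2, from 3720 ± 1020 to 284 ± 49.8 (adjusted p = 1.45e-06). Srebf1 changed by -3.41 ± 0.2, from 3240 ± 308 to 314 ± 101 (adjusted p = 1.59e-06).

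Of 13 peroxisomal and omega oxidation genes in liver 11 rose and none fell by either adjustment (median 1.01, adjusted p = 2.94e-09; adjusted p = 0.0654 with an estimated correlation). Pex11a, a peroxisome division factor, rose by 2.54 ± 0.2, from 143 ± 42 to 823 ± 138. Crat, a carnitine acetyltransferase, rose by 2.15 ± 0.12, from 141 ± 7.25 to 631 ± 62.4. Of 19 genes of mitochondrial fatty acid oxidation 12 rose and none fell, with 13 rises when adjusted over the list alone. Their median was 0.51 (adjusted p = 4.53e-07; adjusted p = 0.105 with an estimated correlation), and the isomerase gene Eci1 rose by 1.25 ± 0.11. Of 17 fasting-responsive PPAR targets 9 rose and none fell, with 12 rises when adjusted over the list alone. The median was 1.26 (adjusted p = 1.25e-05; adjusted p = 0.107 with an estimated correlation). Acot1, an acyl-CoA thioesterase gene, rose by 5.46 ± 0.78, from 2.99 ± 3.66 to 310 ± 346. Angptl4, a lipoprotein lipase inhibitor, rose by 1.48 ± 0.2. Fgf21 was at 74.9 ± 28.7 in fed and 108 ± 40.7 in fasted liver (0.51 ± 0.32, adjusted p = 0.295). Of 13 gluconeogenesis genes 6 rose and 1 fell, or 7 and 1 when adjusted over the list alone. The median was 0.58 (adjusted p = 0.000928; adjusted p = 0.105 with an estimated correlation). Pck1, which makes phosphoenolpyruvate, rose by 1.53 ± 0.12, and Sds, which turns serine into pyruvate, by 4.26 ± 0.25, from 77.2 ± 10.8 to 1600 ± 642.

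**Figure D2:**
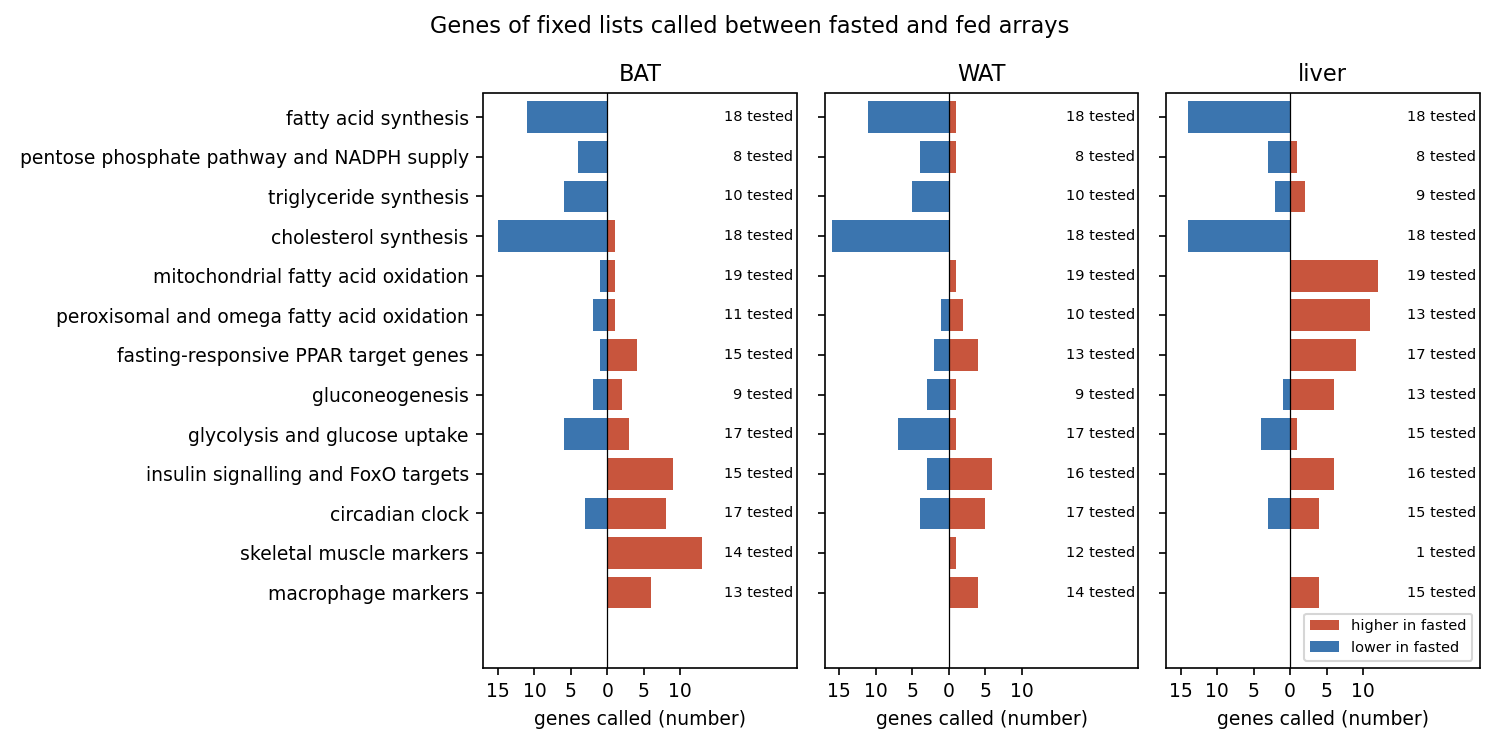
Number of genes called higher (red) and lower (blue) in fasted than in fed arrays in 13 of the fixed lists, in 1 panel per tissue, with the number of list genes tested. Cholesterol synthesis has 15, 16 and 14 falls in BAT, WAT and liver, and mitochondrial fatty acid oxidation has 1, 1 and 12 rises.

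Of 18 fatty acid synthesis genes in liver 14 fell and none rose by either adjustment (median -1.71, adjusted p = 7.93e-16; adjusted p = 0.105 with an estimated correlation). Elovl6 changed by -4.11 ± 0.26, from 1560 ± 536 to 86.3 ± 22.9, and Pnpla3 by -5.02 ± 0.46. Cholesterol synthesis also had 14 falls and no rise among 18 genes by either adjustment (median -1.13, adjusted p = 1.79e-11; adjusted p = 0.187 with an estimated correlation). Msmo1, a sterol oxidase gene, changed by -1.83 ± 0.17, and Dhcr7, a reductase of the last step, by -1.67 ± 0.13. In the pentose phosphate and NADPH list 3 of 8 genes fell and 1 rose by either adjustment (median -0.35, adjusted p = 0.0188; adjusted p = 0.199 with an estimated correlation), with the transketolase gene Tkt at -1.4 ± 0.14. Of 9 glycogen metabolism genes 4 fell and none rose by either adjustment (median -0.44, adjusted p = 0.00389; adjusted p = 0.107 with an estimated correlation). These held Pygl, the liver phosphorylase that breaks glycogen down, at -1.34 ± 0.13, and Ppp1r3b at -1.23 ± 0.17. The glycolysis list was not called, with 1 rise and 4 falls among 15 genes, or 1 and 6 when adjusted over the list alone (adjusted p = 0.0702). With scan day as a block it was called (adjusted p = 0.0322). In it Pklr, the liver pyruvate kinase gene, changed by -2.31 ± 0.21, from 1180 ± 272 to 238 ± 59.6. Triglyceride synthesis had 2 rises and 2 falls among 9 genes, or 3 and 4 when adjusted over the list alone. Its median (0.13) and mean (0.02) were above 0 and its test pointed down (adjusted p = 0.917).

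Of 16 insulin signalling and FoxO target genes in liver 6 rose and none fell, or 7 and 1 when adjusted over the list alone. The median was 0.57 (adjusted p = 0.00297; adjusted p = 0.217 with an estimated correlation), and Irs2 rose by 2.02 ± 0.18. Of 16 autophagy genes 6 rose and 2 fell, or 9 and 2 when adjusted over the list alone. Their median was 0.48 (adjusted p = 0.00297; adjusted p = 0.105 with an estimated correlation). Gabarapl1, an autophagosome protein gene, rose by 1.84 ± 0.1, from 425 ± 22.5 to 1530 ± 104. Of 13 glucocorticoid response genes 4 rose and 1 fell by either adjustment (median 0.07, mean 0.6, adjusted p = 0.047; adjusted p = 0.216 with an estimated correlation). The list's call also ended under 8 other settings, with adjusted p from 0.0527, without fasted animal 9, to 0.211, and without fed animal 1 (0.0728), fed animal 4 (0.0792) or fasted animal 6 (0.0529). Its median was 0.15 without fasted animal 9, 0.12 without fasted animal 6 and 0.04 without fed animal 4. Mt2A, a metallothionein gene, rose by 2.82 ± 0.16, from 1100 ± 260 to 7640 ± 520. Clock genes had 4 rises and 3 falls among 15, or 6 and 3 when adjusted over the list alone, and were not called as a list (adjusted p = 0.733). The clock output factor Dbp rose by 2.39 ± 0.2, and Per2 changed by -1.2 ± 0.11, from 999 ± 64 to 433 ± 43.2. Of 15 macrophage markers 4 rose and none fell, or 7 and none when adjusted over the list alone. Their median was 0.47 (adjusted p = 0.0102; adjusted p = 0.354 with an estimated correlation), and Cd68 rose by 0.66 ± 0.14. Skeletal muscle markers were at a mean log2 level of 3.21 ± 0.21 in fed and 3.37 ± 0.27 in fasted liver.

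Of 10251 genes tested in liver 1850 were called, 968 higher and 882 lower, and 251 and 214 of these changed at least 2-fold. Arrays did not overlap at 23% of genes, against 2.86% by chance. With scan day as a block 2928 genes were called, on the first scan day alone 1531 and on the second 973. The 15 lists called stayed 15 in number with that block and were 15 and 18 within the days. With the block the glucocorticoid list was lost (adjusted p = 0.0571) and the glycolysis list was gained (adjusted p = 0.0322). The share of calls that were higher was 52.32%, against 60% of 640 calls without scaling and 41.52% with median centring. The mean of probe sets ended the calls of Eci1 (adjusted p = 0.156) and Ppp1r3b (adjusted p = 0.177), and the fit without scaling that of Cd68 (adjusted p = 0.0883). On the second scan day alone the call of Pdk4 ended (adjusted p = 0.0815).

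As many shifted lists as with the real groups, 12, 13 and 15 in BAT, WAT and liver, were given by 5, 6 and 2 of the 35 splits of the 8 animals, the real split included. Splits that keep most fed animals together carry part of the fasting effect, so they are not a level for chance alone. Taken list by list, the real split gave the largest mean shift for 12 of the 12 lists called in BAT, 8 of 13 in WAT and 15 of 15 in liver. In WAT it did not for glycogen metabolism (15 of 35 splits as large), glycolysis and glucose uptake (4), the respiratory chain (3), the tricarboxylic acid cycle (2) and macrophage markers (2).

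Many genes changed the same way in the 3 tissues. Of 9168 genes tested in each, 193 rose in all, 215 fell in all and 24 were called in all with mixed directions. Independent lists would give 10.1 rises and 10.7 falls. Pdk4 rose by 1.21 in BAT, 4.56 in WAT and 1.51 in liver, and Irs2, Angptl4, Pck1 and Cpt1a also rose in each. In BAT the call of Cpt1a ended with the muscle covariate (adjusted p = 0.0663) and on the second scan day alone (adjusted p = 0.0588), and its other probe set was at 0.36 (adjusted p = 0.376). Pnpla3 changed by -3.81, -3.06 and -5.02, Elovl6 by -1.88, -1.77 and -4.11, and Ppp1r3b by -1.25, -3.22 and -1.23. BAT and WAT shared 512 rises and 618 falls, with 16 genes opposite, against 116.7, 129 and 245.7 for independent lists. With the muscle covariate these were 103, 108 and 1, without the genes that followed the muscle markers 508, 632 and 16, and without fed animal 2 or fasted animal 8 the shared falls were 388 and 408. Dropping genes leaves the log2 changes of the others as they were. Near equal counts follow from that, here and for the pairs below, and do not test the effect of muscle. BAT and liver shared 326 rises and 310 falls with 80 opposite, against 115.6, 107.4 and 223.5, and 80, 66 and 6 were found with the muscle covariate, 325, 308 and 75 without the genes that followed the markers and 533, 558 and 167 with scan day as a block. WAT and liver shared 257 rises and 286 falls with 48 opposite, against 77.7, 78.1 and 157.1, and the shared falls were 180 with the covariate, 291 without those genes and 438 with the block. Without fed animal 5 WAT and liver shared 150 rises and 169 falls and without fed animal 2 165 and 181, and without fasted animals 6, 8 and 9 the rises were 157, 154 and 155. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.73 between BAT and WAT (Spearman's rho 0.66). It was 0.36 between BAT and liver (rho 0.39) and 0.4 between WAT and liver (rho 0.41). With the muscle covariate Pearson's r of these pairs was 0.58, 0.34 and 0.39. Between BAT and WAT it was 0.65 without fasted animal 10, 0.68 without the genes that followed the muscle markers and 0.75 without fasted animal 6 or 9. Other splits of the same 8 animals gave r of up to 0.67, 0.33 and 0.38. Some of these splits keep most fed animals together and carry part of the fasting effect, so these are not levels for chance alone. The covariances were 0.24, 0.1 and 0.097, against at most 0.101, 0.038 and 0.036 in the other splits.

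**Figure D3:**
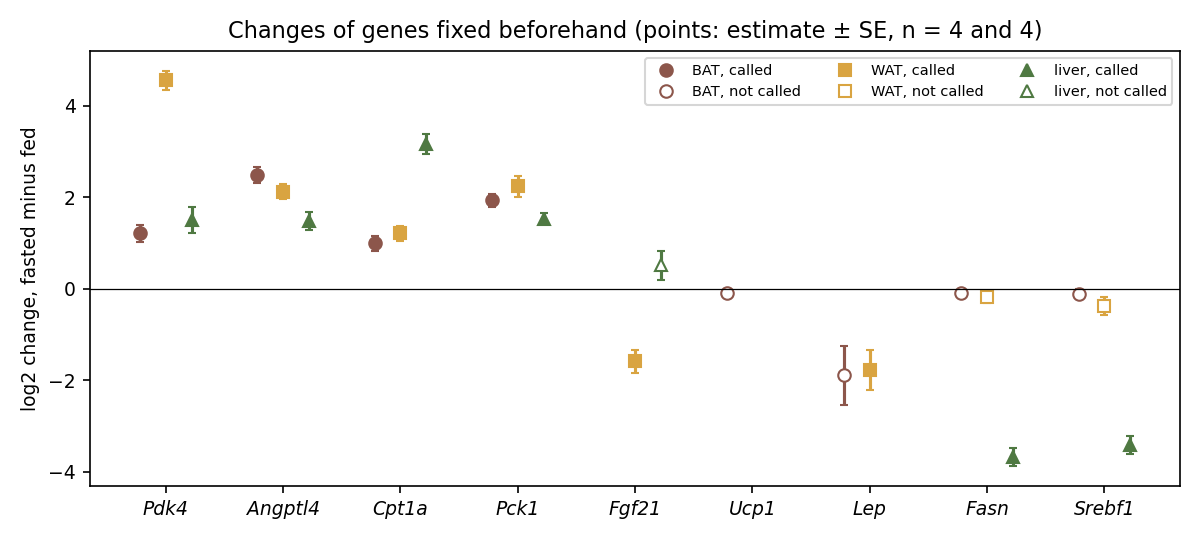
Log2 change, fasted minus fed, of 9 genes fixed by name, by tissue; points are estimates ± SE from n = 4 fed and 4 fasted arrays, filled where called and open where not, and a gene below the signal filter of a tissue has no point. Pdk4, Angptl4, Cpt1a and Pck1 are called higher in each tissue, and Fasn and Srebf1 are called lower in liver (-3.67 and -3.41) and not called in fat.

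Few genes were called with a different fasting effect between BAT and WAT, and this test could miss many. In the simulation, with changes given to BAT alone, 45.3% of log2 differences of 1 and 4.5% of those of 0.5 were recovered. At an unadjusted p under 0.05 in this test there were 1220 of 10799 genes. Pdk4 rose by 1.21 in BAT and 4.56 in WAT (difference -3.36 ± 0.37, adjusted p = 1.21e-05). Its signal was higher in BAT in both states, at 2460 ± 774 in fed and 5500 ± 649 in fasted BAT, against 78.1 ± 14.3 and 1920 ± 485 in WAT. Klf15 rose by 3.43 in BAT and 0.9 in WAT (difference 2.54 ± 0.4, adjusted p = 0.000839). Bambi, a decoy receptor of BMP and TGF-beta signals, was at -0.81 in BAT and 1.32 in WAT (difference -2.14 ± 0.31, adjusted p = 0.000451). Insulin signalling and FoxO targets had higher effects in BAT, with 2 of 16 genes called (median difference 0.49, adjusted p = 2.5e-05; adjusted p = 0.0155 with an estimated correlation). So did circadian clock genes, with 3 of 17 called (median difference 0.48, adjusted p = 4.27e-05; adjusted p = 0.00958 with an estimated correlation). None of 14 skeletal muscle markers was called (list adjusted p = 0.448). Their mean log2 level was 7.22 ± 3.05 in fed BAT and 7.81 ± 4.1 in fasted WAT, and at this spread equal muscle content is not shown. In all, 161 of 10799 genes differed, 85 with the higher effect in BAT and 76 with the lower. Without scaling 35 genes were called, with scan day as a block 346 and without fed animal 2 78, and the animal as a replicate block ended the call of Crb2 (adjusted p = 0.0623), which ended under 11 settings in all (adjusted p from 0.0545 to 0.149). With the mean of probe sets the call of Klf15 ended (adjusted p = 0.415).

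Between BAT and liver the fasting effect differed at genes of several fixed lists. None of 14 skeletal muscle markers was called, with a list median difference of 5.27 (adjusted p = 0.000309; adjusted p = 0.496 with an estimated correlation). Mybpc1, a myosin-binding protein gene, rose by 6.36 in BAT and was at -0.95 in liver, below the signal filter there (difference 7.31 ± 1.98, adjusted p = 0.0182). Its call ended without fed animal 1 or 2 or fasted animal 6 or 8, with adjusted p from 0.0524 to 0.0729. Igfbp1 was at 0.3 in BAT, below the signal filter there, and 5.74 in liver (difference -5.45 ± 0.77, adjusted p = 5.54e-05). Peroxisomal oxidation genes had lower effects in BAT at 8 of 13 genes (median difference -0.87, adjusted p = 6.63e-07; adjusted p = 0.0155 with an estimated correlation). Mitochondrial oxidation genes did at 8 of 19 (median difference -0.42, adjusted p = 7.79e-08; adjusted p = 0.176 with an estimated correlation). Fatty acid synthesis genes had higher effects in BAT at 10 of 18 genes and lower at 2 (median difference 0.95, adjusted p = 5.22e-08; adjusted p = 0.131 with an estimated correlation). As a list these genes fell less in BAT (median change -0.57) than in liver (median change -1.71). Of these genes Fasn, Scd and Thrsp, chosen after their values were seen, had fed BAT signals of 10500 ± 952, 10400 ± 1280 and 9560 ± 1060. Saturation was not excluded at these signals, so the size of the list's difference is uncertain. Among genes chosen after their values were seen, Fasn differed by 3.57 ± 0.22 (adjusted p = 4.58e-10) and Srebf1 by 3.3 ± 0.26 (adjusted p = 3.27e-08). The size of the Fasn difference is uncertain for the same reason. Per2, chosen likewise, rose in BAT and fell in liver (difference 2.49 ± 0.25, adjusted p = 5.21e-07). In all, 1185 of 11212 genes differed, 595 higher and 590 lower in BAT. With scan day as a block 2089 genes were called, without scaling 402 and without fed animal 2 737.

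Between WAT and liver gluconeogenesis genes had lower effects in WAT at 7 of 13 genes (median difference -1.17, adjusted p = 7.8e-05; adjusted p = 0.0155 with an estimated correlation). Peroxisomal oxidation genes did at 6 of 13 (median difference -0.64, adjusted p = 1.08e-05; adjusted p = 0.0272 with an estimated correlation). Fatty acid synthesis genes had higher effects in WAT at 11 of 18 genes and lower at 2 (median difference 1.23, adjusted p = 1.62e-09; adjusted p = 0.0783 with an estimated correlation). As a list these genes fell less in WAT (median change -0.58) than in liver (median change -1.71). The same limit of saturation holds here, with Fasn, Scd and Thrsp at 7600 ± 1230, 7380 ± 789 and 6940 ± 933 in fed WAT. Sds was at -0.56 in WAT, below the signal filter there, and 4.26 in liver (difference -4.82 ± 0.67, adjusted p = 5.53e-05). Fam13a rose by 2.94 in WAT and was at -0.62 in liver (difference 3.56 ± 0.35, adjusted p = 3.93e-07). Fasn (difference 3.48 ± 0.22, adjusted p = 7.07e-10) and Srebf1 (difference 3.05 ± 0.26, adjusted p = 7.32e-08) were chosen after their values were seen, and the size of the Fasn difference is uncertain here too. In all, 847 of 11120 genes differed, 373 higher and 474 lower in WAT. With scan day as a block 1308 genes were called and without scaling 355. The call of Tnnc2 (6.47 ± 1.92, adjusted p = 0.0393), below the signal filter in liver, ended without fed animal 1, 2 or 4 or fasted animal 6, 8 or 10, with adjusted p from 0.0582 to 0.122.

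Fed BAT and fed WAT set the base levels of the fasting effects. Ucp1 was higher in BAT (11500 ± 1310) than in WAT (11.5 ± 9.9), with a fitted difference of 10.17 ± 0.54 (adjusted p = 9.85e-08). Its size is uncertain, since Ucp1 lay below the signal filter in WAT and saturation was not excluded in BAT. Cox8b, a cytochrome oxidase subunit of brown fat and muscle, was at 5100 ± 368 in BAT and 4.71 ± 3.92 in WAT (9.79 ± 0.34, adjusted p = 7.81e-09). Fabp3, a fatty acid binding protein of oxidative tissue, was at 4150 ± 1500 in BAT and 42.5 ± 11 in WAT (6.52 ± 0.23). Star, which carries cholesterol into mitochondria, was at 1630 ± 340 in WAT and 40.1 ± 12.8 in BAT (-5.31 ± 0.22, adjusted p = 1.98e-08). The body-axis genes Hoxc9 (-4.42 ± 0.4) and Hoxa10 (-4.41 ± 0.45) were also higher in WAT. Skeletal muscle markers were at a mean log2 level of 7.22 ± 3.05 in fed BAT and 3.82 ± 0.17 in fed WAT, and Mybpc2, a muscle myosin-binding protein gene, was higher in BAT by 7.11 ± 0.34. Differences against dim signals, as for Cox8b and Mybpc2 in WAT and the Hox genes in BAT, are likewise uncertain in size. Of 10291 genes 4559 differed, 2152 higher in BAT and 2407 higher in WAT, and 783 and 888 of these at least 2-fold. Arrays did not overlap at 42.02% of genes, against 2.86% by chance. Of the calls 47.2% were higher in BAT, against 12.14% without scaling.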

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

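The counts over other splits of the animals, the 3 tests on muscle genes, the scan day tests, the test on the dimmer Srebf1 probe set and Fisher's exact test on bright genes were chosen after the results were seen, and the bound of the scan day test in WAT was changed after its value was seen.

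Muscle genes rose in fasted BAT, and a candidate explanation is skeletal muscle in the excised tissue. Of genes outside the marker list, those that followed the markers among the WAT arrays were 15.79% of the 380 such genes tested in both BAT and WAT that rose at least 2-fold in BAT and 0.48% of 9425 others, a ratio of 33.1, which this explanation needs. The fluidics module as the cause is argued against: the median change of the markers was 0.15 in liver, washed in the same modules, against 5.59 in BAT, the fasted liver arrays lay between 3.06 and 3.65 and the WAT array of fasted animal 6, in module 3, at 4.46, against 12.2 for BAT of fasted animal 6 in that module, and fed animals 4 and 5 lay at 4.57 and 11.52 in BAT, both in module 2, although the WAT arrays high in the markers, fasted 8 (10.87) and 10 (11.83), were the 2 WAT arrays of module 4. A rise of these genes in brown fat cells stays open, since 1 of 4 fed arrays, that of animal 5, lay within 2 log2 units of the lowest fasted array. The marker level goes with feeding in BAT, so the effect of fasting on genes that follow it cannot be told apart from muscle content.

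Batches could contribute to the calls between fed and fasted arrays. Scan day as the whole cause is argued against in BAT and liver by the balance, since each day held 2 fed and 2 fasted arrays. There 100% of the calls stayed with the day as a block. That share adds little, since in a balanced design the block leaves the log2 changes as they were. Scan day as the whole cause is argued against in WAT as well, where 262 genes were called among the 2 fed and 2 fasted arrays of the second day. With the block 89.3% of the calls stayed, under the first bound of 0.9, and 2098 genes were called in place of 1869. The calls that the block ended stay open. The fluidics module follows feeding and cannot be told apart from it; fasted animal 9, washed in WAT in a module of the fed arrays, lay nearer the fasted mean at 89.99% of 1299 genes called without it, and fasted animals 6, 8 and 10, in modules 3 and 4, did so at 90.78, 92.19 and 76.89% of the genes called without each. That is 1 array, and its share lies just under the bound of 0.9 set beforehand.

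Fasn and Srebf1 fell in liver and were not called in fat in the main fit, and saturation of bright probe sets might hide falls in fat. With scan day as a block Srebf1 was called in WAT (-0.4, adjusted p = 0.0201). For Srebf1 this is argued against: its dimmer probe set, with fed signals of 583 in BAT and 524 in WAT, changed by -0.11 and -0.45, against -2.97 in liver. For Fasn saturation stays open, since 0% of 59 genes with a fed BAT signal over 7000 fell at least 2-fold, against 4.53% of 729 genes from 1000 to 3000 (Fisher's exact test, two-sided, p = 0.165). Both probe sets of Fasn were bright in fat, with fed BAT signals of 10500 and 9570. A response of liver that fat lacks, or has to a smaller extent, remains an untested biological explanation.

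Of the 35 splits of the 8 animals into 4 and 4, 1, the real split, gave as many genes in BAT (2780, highest other 21), in WAT (1869, highest other 1) and in liver (1850, highest other 269). It was also 1 of 35 for the differences between BAT and WAT (161, highest other 106), BAT and liver (1185, highest other 57) and WAT and liver (847, highest other 265) and for the shared calls of these pairs (1130, 636 and 543, highest others 0, 2 and 0). For fed BAT against fed WAT the 35 splits are of the 8 arrays of the 4 fed animals, and the real split was again 1 of 35 (4559, highest other 0, also among the 8 splits that part the arrays of every animal). The real split alone reached each count, and 1 of 35 is the smallest share these splits can give, so chance is not excluded. For BAT against WAT the real count itself fell under 106 without fed animal 2 or 4, without fasted animal 6 or 8 and without scaling. It was 106 without fasted animal 9. Other splits called at most 21 genes in BAT and 1 in WAT, so their shared calls had to be few. The comparison of shared calls therefore does not test agreement between tissues. The highest other count in BAT, in liver and in the 3 differences came from the split by scan day. For the number of shifted lists, 5 of 35 splits gave as many in BAT (12, highest other 14), 6 in WAT (13, highest other 15) and 2 in liver (15, highest other 15). Splits that keep most fed animals together still carry part of the fasting effect. These counts are therefore not a level for chance alone, and chance is not excluded. Taken list by list, the real split gave the largest mean shift for 12 of 12 called lists in BAT (cholesterol synthesis 1.2, highest other 0.72; muscle markers 4.82, highest other 4.67; macrophage markers 0.45, highest other 0.44), 8 of 13 in WAT and 15 of 15 in liver. In WAT as large a shift came from 15 splits for glycogen metabolism (0.2, highest other 0.5), 4 for glycolysis (0.21, highest other 0.27), 3 for the respiratory chain (0.26, highest other 0.35) and 2 each for the tricarboxylic acid cycle (0.27, highest other 0.28) and macrophage markers (0.36, highest other 0.39).

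Single arrays stood apart from the other 3 of their group in 20 of 302 groups checked, or 6.62%, where chance gives about 1 in 20. In fed BAT these were animal 5 for Mybpc1 (signal 546) and Myl2 (243), animal 4 for Agpat2 (8090) and animal 1 for Fkbp5 (85.3) and Per3 (32.5). In fasted BAT they were animal 9 for Slc2a5 (10.1), animal 8 for Elovl6 (1230) and Cyp2e1 (767) and animal 6 for Cd68 (265). In fed WAT they were animal 1 for Mogat2 (88.8) and animal 4 for Mvd (228). Fasted WAT had animal 6 for Pdk4 (1210), animal 9 for Oxtr (20.4), animal 8 for Mlxipl (122) and animal 10 for Cyc1 (2700). In liver they were fed animal 4 for Pnpla2 (138), fasted animal 6 for Eci1 (5240) and Bnip3 (943) and fasted animal 8 for Crat (724) and Abcg5 (775).

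The interaction test called these differences of the fasting effect, BAT minus WAT: Klf15 2.54, Cyp2e1 2.52, Sh3bp4 2.12, Sowahc 1.98, Ppp1r3b 1.97, Tnfrsf12a 1.88, Pdk4 -3.36, Crocc -3.36, Crb2 -3.04, Rprml -2.75, Id2 -2.22 and Bambi -2.14. The call of Cyp2e1 ended under 7 settings (adjusted p from 0.0586 to 0.161), among them without fed animal 2 or fasted animal 6, 8 or 10, that of Tnfrsf12a without fed animal 2, 4 or 5 or fasted animal 8 or 9 (0.0625 to 0.11), that of Crocc without fed animal 2 (0.0619), and that of Ppp1r3b with the mean of probe sets (0.0974). For BAT minus liver they were Mybpc1 7.31, Myl2 6.85, Ampd1 6.17, Myoz1 6.15, Cmya5 6.14, Myoz2 6.12, Nim1k -5.68, Igfbp1 -5.45, Acot1 -4.26, Colq -3.93, Acot4 -3.68, Sds -3.4, Fasn 3.57, Srebf1 3.3 and Per2 2.49. The call of Myoz1 ended under 8 settings (adjusted p from 0.0611 to 0.15), among them without fed animal 1, 2 or 4 or fasted animal 6, 8 or 9. Those of Myoz2 (0.0634 to 0.0862) and Myl2 (0.0598 to 0.0741) ended without fed animal 1, 2 or 4, that of Myoz2 also without fasted animal 8, and that of Ampd1 without fed animal 2 (0.072) or 4 (0.0505). For WAT minus liver they were Tnnc2 6.47, Stac3 4.14, Gsta3 3.8, Kcnj15 3.69, Slc34a2 3.61, Fam13a 3.56, Igfbp1 -5.78, Acot1 -5.01, Sds -4.82, Nim1k -4.35, Prss35 -3.8, Colq -3.73, Fasn 3.48, Srebf1 3.05 and Per2 2.02. Without the WAT arrays of fasted animals 8 and 10 the call of Stac3 ended (adjusted p = 0.0649). Some of these genes lay below the signal filter in 1 tissue of the pair, where the size of a difference is uncertain. In BAT against WAT these were Crocc and Crb2, in WAT. In BAT against liver they were Nim1k, Igfbp1, Acot1 and Sds in BAT and Mybpc1, Myl2, Ampd1, Myoz1, Cmya5 and Myoz2 in liver. In WAT against liver they were Gsta3, Kcnj15, Slc34a2, Igfbp1, Acot1, Sds, Nim1k and Colq in WAT and Tnnc2 and Prss35 in liver.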

How the results depend on the processing

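The scan days alone, the muscle covariate, the lymphocyte covariate in WAT, the runs without genes that followed the muscle markers and the run without the WAT arrays of fasted animals 8 and 10 were chosen after seeing the data. With the lymphocyte covariate 13 of 13 list calls and 48 of 48 named gene results in WAT stayed on the same side of the threshold. Over the settings fixed beforehand the values of named genes kept their direction, with 3962 on the same side of the threshold, 85 no longer past it and 20 newly past it; over the added ones these were 543, 62 and 5, and 5 reversed. The cause of the changes below was not tested, except that fits on fewer arrays have fewer samples and fits on all probe sets test more features. Dim genes are limited by signal over background. The animal as a replicate block gave 175 calls between BAT and WAT, 1311 between BAT and liver, 948 between WAT and liver and 4688 for fed BAT against WAT, and besides Crb2 changed no call of a named gene.

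Without scaling, calls were 1791 in BAT (855 higher), 655 in WAT (170 higher, 485 lower, 120 at least 2-fold higher) and 640 in liver (384 higher, 256 lower), with 7 lists higher in WAT; 35 between BAT and WAT (22 higher, 13 lower), 402 between BAT and liver (157, 245) and 355 between WAT and liver (75, 280); and for fed BAT against WAT 713 higher and 5162 lower, 296 and 2615 at least 2-fold. Median centring gave 463 higher in WAT, 47 lower between BAT and WAT and 225 higher between WAT and liver. All probe sets gave 752 and 474 at least 2-fold in BAT, 1346 higher with 428 and 419 at least 2-fold in WAT, 1461 higher with 500 and 333 in liver, and 6864 for fed BAT against WAT (3813 lower, 1227 and 1591 at least 2-fold). The mean of probe sets gave 107 between BAT and WAT (55 higher).

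Scan day as a block gave 2928 in liver (1533 higher, 1395 lower), 346 between BAT and WAT (198, 148), 2089 between BAT and liver (1001, 1088) and 1308 between WAT and liver (563, 745); shared calls of BAT and liver were 533 higher, 558 lower and 167 opposite, and of WAT and liver 438 lower and 86 opposite. Module as a random block gave 3209 in liver (1691, 1518), 349 (194, 155), 2061 (1026, 1035) and 1343 (598, 745). In BAT and liver each module held fed or fasted arrays alone, so this block could not remove an effect of the module. The higher counts are therefore no sign that the calls hold against it. The first scan day alone gave 1203 in BAT (583, 620, 272 at least 2-fold higher) and, from 2 fed arrays and the 1 fasted array of animal 10, taken to vary like the others, 936 in WAT (399, 537). The second gave 874 lower in BAT with Srebf1 at 0.03, 262 in WAT (110, 152, at least 2-fold 94 and 137) with 7 lists higher, and 973 in liver (510, 463).

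The muscle covariate gave 372 in BAT (202, 170, at least 2-fold 169 and 130), with Ckm at -0.37, Myh4 at -0.57, Atp2a1 at -0.33, Fasn at 0.01 and 7 lists (3 higher), and 1105 in WAT (529, 576). The muscle list's shift was -0.06 in BAT and -0.34 in WAT. Shared calls were 103, 108 and 1 opposite for BAT and WAT, 80, 66 and 6 for BAT and liver, and 180 lower and 21 opposite for WAT and liver. Without the genes that followed the muscle markers BAT gave 2663 and WAT 1892, and BAT and WAT shared 508, 632 and 16. The genes that stay keep their log2 changes in this run, so it does not test the effect of muscle on them. Without the WAT arrays of fasted animals 8 and 10 WAT gave 1044 (485, 559), with 128 higher between BAT and WAT. With an estimated correlation 0 lists were called by camera in any tissue, of 12, 13 and 15, and fry called 8 lower in BAT and 9 in liver. Of the 40 list calls 37 held with fry. At least 2-fold, shared calls were 104, 104 and 1 opposite, then 54, 40 and 7, then 39, 35 and 3. Without a filter, opposite calls were 10 for BAT and WAT and 29 for WAT and liver.

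Leaving out each animal in turn gave 2195 to 2573 in BAT (higher 1161 to 1347, lower 1024 to 1226, at least 2-fold 451 to 529 and 272 to 314), 1172 to 2209 in WAT (555 to 1078, 617 to 1131, 192 to 259 and 206 to 253) and 1404 to 1644 in liver (701 to 879, 682 to 765, 227 to 286 and 191 to 226). Lists ran from 11 to 14 in BAT (6 to 7 higher, 5 to 7 lower), 10 to 14 in WAT (3 to 5, 7 to 10) and 13 to 17 in liver (8 to 11, 5 to 6). Differences ran from 78 to 167 for BAT and WAT (40 to 91, 38 to 76), 737 to 1118 for BAT and liver (362 to 590, 375 to 528) and 574 to 767 for WAT and liver (253 to 313, 313 to 454), and fed BAT against WAT from 3380 to 3947 (1648 to 1884, 1732 to 2063, 702 to 842 and 716 to 1013). Shared calls ran from 343 to 502 higher, 388 to 558 lower and 6 to 14 opposite for BAT and WAT, 226 to 261, 215 to 250 and 37 to 55 for BAT and liver, and 150 to 255, 169 to 250 and 18 to 38 for WAT and liver. Counts moved by over 1.5 times in WAT without fed animal 5 (1172), fed 2 (634 lower), fasted 6 (591 higher) and fasted 9 (576 higher). Between BAT and WAT they did without fed 2 (78), fed 4 (102), fed 5 (46 lower), fasted 6 (88), 8 (97) and 9 (106), between BAT and liver without fed 2 (737) and fasted 8 (390 higher), and between WAT and liver without fasted 8 (313 lower). Shared calls did for BAT and WAT without fed 2 (388 lower) and fasted 8 (408 lower), and for WAT and liver without fed 2 (165 higher, 181 lower), fed 5 (150, 169) and fasted 6, 8 and 9 (157, 154 and 155 higher). Opposite calls did for BAT and WAT without fed 2, 4 and 5 and fasted 6, 8 and 9, for BAT and liver without fed 1, 2 and 5 and fasted 6, 8, 9 and 10, and for WAT and liver without fed 2, 4 and 5 and fasted 6, 8, 9 and 10.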

Other observations

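In fasted liver, endoplasmic reticulum chaperone genes moved both ways. Of 20 genes 8 fell, 3 rose and 9 did not pass, or 10 and 4 when adjusted over the list alone (median -0.31, adjusted p = 0.0131; adjusted p = 0.216 with an estimated correlation; adjusted p = 0.0503 with quantile normalization). Creld2, a chaperone of the reticulum, changed by -1.49 ± 0.19, from 1140 ± 322 to 396 ± 54.3. Xbp1, a transcription factor of the unfolded protein response, rose by 1.04 ± 0.13 in liver. Of 14 bile acid and sterol disposal genes 5 rose and none fell, or 7 and none when adjusted over the list alone (median 0.33, adjusted p = 0.0394; adjusted p = 0.284 with an estimated correlation). This call also ended under 8 other settings, with adjusted p from 0.0527, without fasted animal 9, to 0.157, and without fed animal 1 (0.106) or fed animal 4 (0.0582). Nr0b2, a nuclear receptor that represses bile acid synthesis, rose by 2.59 ± 0.36, from 165 ± 69.2 to 1040 ± 453. Abcg5, a sterol exporter, rose by 1.68 ± 0.24. Of 6 adipokine and secreted factor genes in liver 3 rose and none fell, or 4 and none when adjusted over the list alone. The median was 0.52 (adjusted p = 0.0119, and 0.234 with an estimated correlation). Without a filter the median was 0.12 and the call ended (adjusted p = 0.0964).

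Of 15 amino acid starvation genes 2 rose and 3 fell in BAT, 2 and 3 in WAT and 1 and 4 in liver, with 10 not passing in each; adjusted over the list alone these were 3 and 3, 3 and 4, and 3 and 5. Of members chosen after their values were seen, Trib3, an inhibitor of Akt signalling, rose by 1.66 ± 0.19 in BAT, 1.18 ± 0.27 in WAT and 2.55 ± 0.27 in liver. Psph, which makes serine, changed by -0.73 ± 0.17, -1.68 ± 0.2 and -1.96 ± 0.18. The list was not called in BAT, WAT or liver (adjusted p = 0.785, 0.253 and 0.0847), and in BAT its median was -0.34 and its mean 0.09.

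Lymphocyte markers differed between WAT arrays, with mean log2 levels of 8.15 in fed animal 1, 7.31 in fasted animals 6 and 8 and from 3.96 to 5.07 in the other 5. Mesothelium markers were at 7.55 in fasted animal 6 and from 4.41 to 5.47 on the other WAT arrays.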
